A study of Mus musculus with 24 samples.

How the data were processed

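RNA was measured in 24 libraries from day 7 bone marrow stromal cultures of wild type and Sh3bp2 knock-in mice, 6 libraries for each genotype in each of the 2 sorted populations. Per the labels' protocols, ribosomal RNA was depleted from total RNA, stranded libraries were made with a SMARTer kit, and paired ends were sequenced on a NextSeq. The deposited files hold 1 whole-number count per gene and library, not normalised. Per the submitters' processing notes, FastQC 0.11.7, MultiQC, HTSeq 0.9.1 and DESeq2 1.20.0 were used with the mouse build GRCm38 (mm10). The aligner and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes were treated as uncertain. Reads shared by near-identical genes, such as Ly6a and Ly6i, the H2 genes, Mt2 and its relatives, Gsta3 and the histones, could have been split or dropped by the counting, and their values carry that doubt.

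The count tables listed 54232 gene identifiers, of which 54165 matched the GENCODE annotation of GRCm38 used for symbols and coordinates, and 31499 had at least 1 count. Totals per library ranged from 9875390 to 15826711. The mitochondrial ribosomal RNA mt-Rnr2 took the largest share, 3.25% to 6.42% of a library. Replicates of a group were compared pairwise by a chi-square statistic per degree of freedom, which ranged from 7.23 to 65.0, so no pair was within counting noise and none was merged. A prefix in the names of the deposited files was read as marking 2 sequencing runs, with 3 libraries of each group in each, and the run was a term in every fit. No label states the runs, so every result by run rests on that reading. Same-numbered replicates were not treated as pairs.

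Tests were run in R 4.3.3. Genes were kept with edgeR 4.0.16's filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood test (robust fit), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Each genotype comparison used the 12 libraries of its population. The interaction and the population comparisons used all 24. CPM values are counts scaled to a common library total with TMM factors, and fold changes are knock-in over wild type unless stated. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry (limma 3.58.1), on voom log2 values, over lists with 5 or more tested genes. Of the 41 lists, 36 were tested in hematopoietic cells, 32 in mesenchymal cells and 37 for the interaction. Camera called 11, 11 and 4 of them. With an estimated correlation it called 0 in each, with 1, 2 and 1 lists at an unadjusted p under 0.05, while fry called 8, 5 and 1.

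The comparisons, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Sh3bp2, Ptprc, Ly6a, Tnf, Csf1, Tnfsf11, Tnfrsf11b and Runx2 always. It then took the 6 largest rises and 6 largest falls among called genes averaging 1 CPM or more in the higher group, without predicted genes, pseudogenes and receptor segments. It added up to 4 called members, by adjusted p, of each list that passed camera or held 3 or more called genes, and up to 4 members of each cell type list in the population comparisons. The text gives a part of the genes so named, and a gene that the rule named is not reported here. Ctsk in the text of hematopoietic cells, the levels of Mmp9, Acp5 and Atp6v0d2 there, the osteoclast genes Calcr, Ostm1, Oscar, Ocstamp, Dcstamp and Tnfrsf11a, and the interaction values of genes named for a single population were chosen after their values were seen.

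The share of RNA from the other population was estimated per library from 21 stromal or 16 leukocyte markers averaging 10 CPM or more in the population they mark, as the median over markers of their level relative to that population in the same genotype. In simulated mixtures the estimate of stromal RNA erred by up to 0.15 percentage points at a share of 2% and 1.5 at 20%. That of leukocyte RNA erred by up to 0.0306 at 0.1% and 0.093 at 1%. Every stromal estimate fell below the known share, at 18.5% to 19% for 20%. The mixtures assume that the marked genes are silent in the other population. They also used the mean profile by which the estimate divides, so these errors do not cover variation of that profile between libraries. For the subtraction, that share of the other population's mean profile, in the same genotype, was taken from each library's counts and the test was repeated. Counts were stopped at 0, so a fold change after the subtraction can be too large where few counts are left in a group.

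The tests were checked on counts simulated from the means, library sizes and dispersions of the real genes, with changes of 1.5, 2 and 4-fold in 200 genes. Before these changes each gene had the same mean in every group and run. The interaction and population rates therefore do not cover genes largely confined to 1 population. In hematopoietic cells (14030 genes) 43.3%, 74.6% and 95.5% of the changed genes were recovered, and 3.01% of calls were false. In mesenchymal cells (13867 genes) the shares were 37.3%, 68.7% and 93.9%, with 3.92% false. For the interaction (15389 genes) they were 16.4%, 52.2% and 81.8%, with 1.94% false, and for wild type populations (15389 genes) 34.3%, 64.2% and 93.9%, with 4.08% false. Changes under 2-fold were therefore often missed at this depth and number of libraries, most of all for the interaction.

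Alternatives covered DESeq2 1.42.0's size factors and its Wald test, no filter on low counts, no run term, the replicate number or the culture number as a block, all 24 libraries in 1 fit, each run alone and each library left out. The subtraction and a fit without libraries of high stromal share were added after seeing the data. The culture numbers in the file names differ from the replicate numbers of the titles, and groups were taken from the titles.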

Results

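The study profiled RNA from bone marrow stromal cultures of female C57BL/6 mice that were wild type or carried a knock-in on both copies of Sh3bp2. The mice were 6 to 8 weeks old. Sh3bp2 encodes an adaptor protein that couples immune receptors to kinases such as SYK and SRC. Mutations of the human gene cause cherubism, a childhood disease of the jaw with inflammation and many osteoclast-like cells, and the series is titled as a mouse model of it. After 7 days the cells were sorted on CD45, the leukocyte surface protein encoded by Ptprc, and Sca1, encoded by Ly6a. Cells positive for both markers were taken as hematopoietic, and cells positive for Sca1 alone as mesenchymal. Each combination of genotype and population held 6 libraries, 24 in all. Total counts per library ranged from 9875390 to 15826711, with a mean of 13357727 ± 1573115 (SD, n = 24). The group means were 12859955 in wild type hematopoietic, 12993057 in knock-in hematopoietic, 14001185 in wild type mesenchymal and 13576710 in knock-in mesenchymal libraries. The labels do not say whether replicates came from separate animals or cultures, so the p-values measure only the spread between these samples.

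The first comparison asked what the sort separated. Hematopoietic libraries carried the genes of macrophages and other leukocytes, and mesenchymal libraries those of stromal and bone-forming cells. Ptprc averaged 787 ± 60.6 CPM, counts normalised to library size, (SD, n = 6) in wild type hematopoietic libraries against 2.99 ± 1.88 in wild type mesenchymal ones, a log2 fold change of -8.06 (mesenchymal over hematopoietic, SE 0.41, adjusted p = 2.84e-14, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Stromal genes went the other way, with log2 fold changes of 3.48 for the mesenchymal transcription factor Prrx1 and 4.05 for the growth factor receptor Pdgfra. All 16 tested leukocyte markers and all 24 macrophage and monocyte markers were lower in mesenchymal cells of either genotype by the same edgeR test, and 22 of 24 stromal markers were higher in wild type, with the same counts adjusted over the list alone. Camera called these lists in wild type cells (adjusted p = 1.67e-10, 5.04e-12 and 4.09e-08), but not with an estimated correlation (adjusted p = 0.0692, 0.0692 and 0.248 with an estimated correlation). Examples were the myeloid receptor Trem2 at -7.57, its signalling partner Tyrobp at -8.07 and the leukocyte tetraspanin Cd53 at -8.35 on the log2 scale. Of 15389 tested genes, 5451 were higher and 5853 lower in wild type mesenchymal cells, and 5224 were higher and 6011 lower in knock-in mesenchymal cells.

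Sh3bp2 followed the leukocytes. It averaged 210.7 ± 27.2 CPM in wild type hematopoietic cells and 7.43 ± 0.777 CPM in wild type mesenchymal cells (SD, n = 6 each), a log2 fold change of -4.83 (SE 0.12, adjusted p = 1.48e-19 by edgeR). Tnf, the inflammatory cytokine, was also a hematopoietic transcript, at -8.99 on the log2 scale (adjusted p = 5.67e-14). Csf1, Tnfsf11, Tnfrsf11b and Runx2 were higher on the mesenchymal side. Csf1, the macrophage growth factor, stood 3.76 higher in log2 in wild type mesenchymal cells (adjusted p = 3.06e-15 by edgeR). Tnfsf11, which encodes the osteoclast inducer RANKL, stood 3.60 higher, Tnfrsf11b, which encodes its decoy receptor osteoprotegerin, 3.29 higher, and Runx2, the osteoblast transcription factor, 2.60 higher. Ly6a, the Sca1 gene used in both gates, was low in all groups, with means from 9.99 to 11.9 CPM and a wild type population difference of -0.22 (SE 0.41, adjusted p = 0.644 by edgeR). Among genes averaging 1 CPM or more in the higher group, the largest rises in wild type mesenchymal cells included the prostaglandin receptor Ptgfr (5.48) and the adipokine Adipoq (5.40), and the largest falls included Lilra6 (-10.37) and the cytokine Osm (-9.56). In knock-in cells the aminopeptidase Enpep stood 5.70 higher and the coagulation factor F10 was at -9.76.

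Markers of the other population had counts in every library. Stromal marker genes put the share of mesenchymal RNA in hematopoietic libraries at 10.6% ± 4.66 in wild type and 11.3% ± 6.16 in knock-in (SD, n = 6 each, two-sided exact permutation p = 0.781), with single libraries from 4.98% to 22.99%. Leukocyte markers put hematopoietic RNA in mesenchymal libraries at 0.466% ± 0.167 in wild type and 0.641% ± 0.358 in knock-in (n = 6 each, exact permutation p = 0.29).

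**Figure D1:**
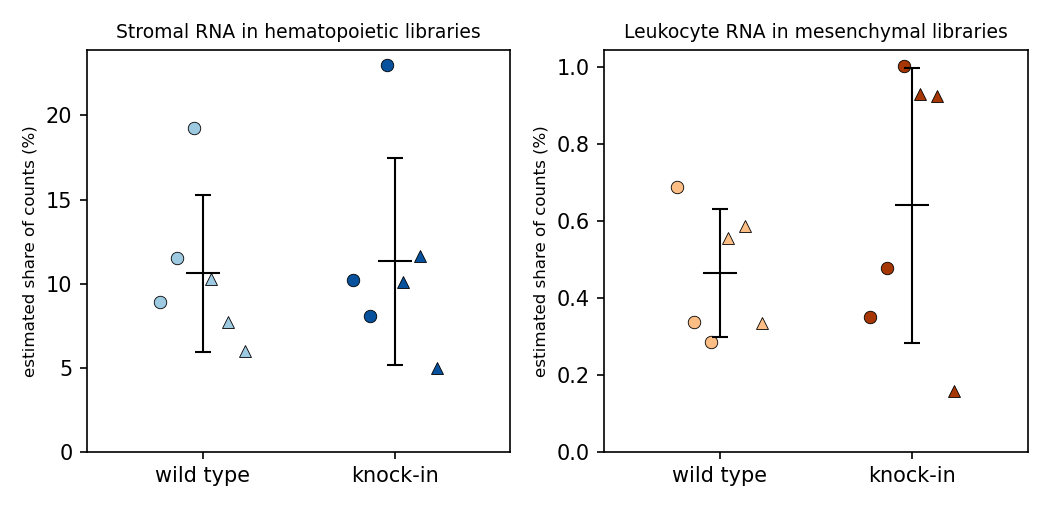
Share of counts (%) estimated to come from the other sorted population, per library, by genotype. Circles are libraries of sequencing run 1, triangles those of run 2, and bars show the mean and SD of 6 libraries. Stromal RNA averaged 10.6% and 11.3% of hematopoietic libraries, and leukocyte RNA 0.466% and 0.641% of mesenchymal ones.

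The second comparison asked what the Sh3bp2 knock-in changed in hematopoietic cells. Of 23 tested genes of bone-resorbing osteoclasts 16 rose by edgeR, among them the transcription factor Nfatc1 and the acid-producing enzyme Car2, as did 19 of 33 genes of glycolysis and the hypoxia response. Both lists passed camera at its preset correlation and fry (fry adjusted p = 0.00481 and 0.00883), but not camera with an estimated correlation (adjusted p = 0.729 for each). Fry called 5 of the 11 lists that camera called. The mannose receptor Mrc1, a marker of resident macrophages, fell from 2284 ± 325 to 827 ± 177 CPM (SD, n = 6 each). Of 14030 tested genes, edgeR's quasi-likelihood test called 1264 higher and 967 lower in knock-in cells at a Benjamini-Hochberg adjusted p under 0.05, 2231 in all. At least a 2-fold change was fitted for 450 of the former and 213 of the latter. With each sequencing run fitted alone, 3 libraries against 3, the test called 672 genes in run 1 and 218 in run 2. Neither run alone called Tnfrsf11b, Insc, Herc6, Cdkn1a, Cd79a, Sp7, Tyms, Nfatc1, Kitl, Cxcl1 or Cxcl2 (adjusted p-values from 0.05002 to 0.391), which all 12 libraries did. In 52 of the 89 named genes, which were picked among the called ones, all 6 knock-in libraries lay beyond every wild type library in the direction of the change, and in 84 beyond the wild type mean.

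Sh3bp2 (ENSMUSG00000054520, chromosome 5, 34525838 to 34563641 in GRCm38, a protein-coding gene) averaged 234 ± 37.9 CPM in knock-in hematopoietic cells (SD, n = 6) against the wild type 210.7 CPM. Its log2 fold change was 0.15 (SE 0.12, adjusted p = 0.448 by edgeR). The labels do not say what the knock-in alters in the transcript, so this level does not check the genotype. Ptprc was at -0.07 (adjusted p = 0.692) and Ly6a at -0.11 (adjusted p = 0.914) in the same edgeR fit. The cytokine Tnf averaged 22.5 ± 6.97 CPM in wild type and 22.8 ± 12.04 CPM in knock-in cells (n = 6 each), a log2 fold change of 0.03 (SE 0.23, adjusted p = 0.955 by edgeR). Csf1 was at 0.01 (SE 0.15, adjusted p = 0.975).

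Osteoclast genes showed the largest median shift among the 36 lists tested. Of 23 tested genes 16 rose by edgeR (18 adjusted over the list alone), with a median log2 fold change of 2.42. The list passed camera at an adjusted p of 1.49e-11 (1.11e-10 in run 1 alone and 4.75e-11 in run 2 alone), with an adjusted p = 0.729 with an estimated correlation, and fry, which tests whether the genes of a list move on balance one way, gave an adjusted p of 0.00481. Jdp2, an AP-1 factor needed for osteoclast differentiation, rose from 53.5 ± 20.8 to 288 ± 70.6 CPM (SD, n = 6 each; log2 fold change 2.42, SE 0.25, adjusted p = 0.000102 by edgeR). Src, the kinase that organises the resorbing edge of the cell, rose from 18.6 ± 8.48 to 129 ± 32.2 CPM (2.81, SE 0.30, adjusted p = 0.000123 by edgeR). The proton-chloride exchanger Clcn7 rose by 0.79 and Nfatc1, the lineage's inducing transcription factor, by 1.30 on the log2 scale. Car2 rose by 4.11 (SE 0.60, adjusted p = 0.000766 by edgeR), from 0.564 to 9.96 CPM. The resorption gene Ctsk was at 2.33 (SE 0.90, adjusted p = 0.108 by edgeR) and was not called.

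**Figure D2:**
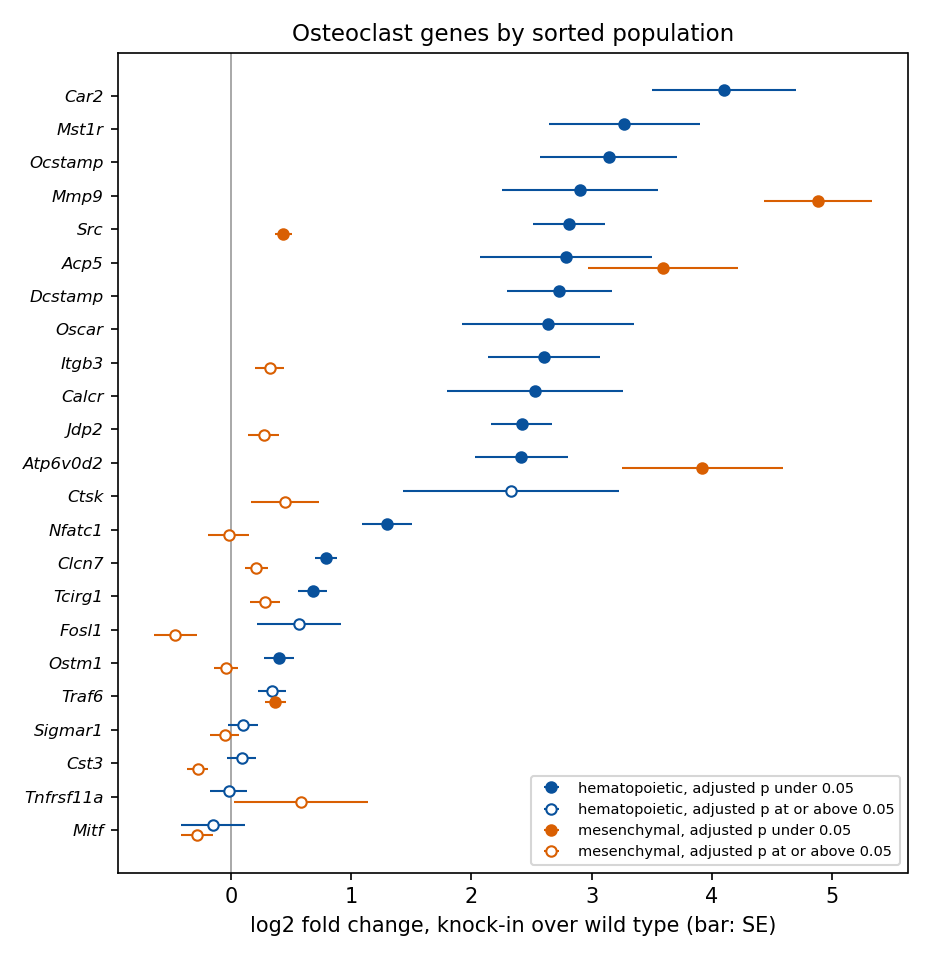
Log2 fold change (knock-in over wild type) of the osteoclast genes tested in hematopoietic and mesenchymal cells, with SE as bars. Filled points have an adjusted p under 0.05 by edgeR and open points do not. In hematopoietic cells 16 of 23 genes were higher in the knock-in, and in mesenchymal cells 5 of 17.

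The largest single rises in hematopoietic cells were in Slc6a12, a betaine and GABA transporter (log2 fold change 6.38, SE 0.69), the Ly6 family gene Ly6i (4.33), the caveolar coat gene Cav1 (4.28), Tnfaip8l3 (4.23), Car2 and the giant muscle protein gene Ttn (4.003), with edgeR adjusted p-values from 7.55e-06 to 0.000766. Cav1 went from 17.3 ± 6.11 to 340 ± 148 CPM (SD, n = 6 each). The largest falls were in the sodium-calcium exchanger Slc8a3 (-3.52), the proprotein convertase Pcsk6 (-3.39), the channel gene Panx3 (-3.39), Insc (-2.96), the prostaglandin-degrading enzyme Hpgd (-2.91) and the urea transporter Slc14a1 (-2.89). Hpgd went from 134.5 ± 88.8 to 18.2 ± 7.05 CPM. Panx3 (adjusted p = 0.0305 by edgeR) lost its call without any 1 of wild type replicates 2 and 4 or knock-in replicates 1, 2, 3, 4 and 6, with adjusted p-values up to 0.0734, and without the filter on low counts (0.108). After the estimated stromal RNA was subtracted, Slc8a3, Pcsk6, Panx3 and Insc had too few counts to be tested, while the other 8 of these 12 genes kept their calls.

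Metabolic genes moved in the same cells. In the glycolysis and hypoxia list 19 of 33 genes rose and 1 fell (22 and 1 adjusted over the list alone), and the list passed camera (adjusted p = 6.12e-08, and adjusted p = 0.729 with an estimated correlation). The glycolytic enzymes Aldoa (0.74), Eno1 (0.78) and Hk1 (0.46) and the hypoxia-induced oxidase Ero1l (0.66) had edgeR adjusted p-values from 0.000161 to 0.00107. Of 17 antioxidant genes controlled by NRF2 and related factors, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with a camera adjusted p of 0.00328 and an adjusted p = 0.729 with an estimated correlation. Mt2, a metal-binding metallothionein, rose by 2.30, the cystine importer Slc7a11 by 2.89 and the glutathione transferase Gsta3 by 2.99 on the log2 scale. Of 19 genes of the p53 and senescence list 3 fell by edgeR (7 adjusted over the list alone; camera adjusted p = 0.00799, and adjusted p = 0.729 with an estimated correlation), among them the cell cycle inhibitor Cdkn1a (-0.83) and Sesn1 (-0.66).

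Immune genes were split between rises and falls. Among 34 genes of Toll-like receptor and NF-kB signalling 13 rose and 6 fell (13 and 7 adjusted over the list alone), and camera did not call the list (adjusted p = 0.0868). The NF-kB feedback inhibitor Nfkbia rose by 1.10 (SE 0.13), its relative Bcl3 by 1.02 (SE 0.12) and the receptor adaptor Traf1 by 2.34 (SE 0.28) on the log2 scale, with edgeR adjusted p-values from 0.000115 to 0.00018. Genes of the Fc receptor and ITAM pathway in which the SH3BP2 protein acts moved both ways, 7 of 38 up and 9 down (8 and 9 adjusted over the list alone). That list had a median log2 fold change of -0.10 and a mean of 0.13, and camera pointed down (adjusted p = 0.49). Its risers included the kinase Fgr (2.08) and the lectin receptor Clec4e (2.84). Of 24 macrophage and monocyte markers 3 rose and 9 fell (3 and 11 adjusted over the list alone), with Mrc1 at -1.47, the Fc receptor Fcgr1 at -1.26 and the chemokine receptor Ccr2 at -1.62. This list passed camera narrowly (adjusted p = 0.0482, and adjusted p = 0.729 with an estimated correlation). It did not pass without wild type replicate 2 (0.0689), wild type replicate 4 (0.0735) or knock-in replicate 2 (0.063), in run 2 alone (0.105) or after the stromal subtraction (0.065).

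Of 36 interferon-stimulated genes 5 fell by edgeR (8 adjusted over the list alone), with a median log2 fold change of -0.52 and a camera adjusted p of 4.23e-06, against an adjusted p = 0.729 with an estimated correlation and 0.207 by fry. Herc6, a ubiquitin ligase induced by interferon, was at -0.50 (adjusted p = 0.0197 by edgeR). It was not called without wild type replicate 2 (0.0548), in either run alone (0.0968 and 0.359) or in 1 fit of all 24 libraries (0.119). Of 11 B lineage genes the antigen receptor chain Cd79a fell by 2.20 (SE 0.53, adjusted p = 0.0124 by edgeR), the 1 member called (1 adjusted over the list alone), with a camera adjusted p of 0.00697, an adjusted p = 0.729 with an estimated correlation, and 0.058 in run 2 alone. Among 40 cell cycle genes the replication clamp Pcna (-0.45) and thymidylate synthase Tyms (-0.64) were the 2 that fell (2 adjusted over the list alone). Camera called that list (adjusted p = 0.0111, and adjusted p = 0.78 with an estimated correlation), but not without wild type replicate 6 (0.156), knock-in replicate 3 (0.065) or knock-in replicate 6 (0.173), and in run 1 alone it pointed up (0.201). Of 23 cholesterol synthesis genes 2 fell (none adjusted over the list alone), and of 17 replication histone genes 1 fell (1 adjusted over the list alone). Both lists passed camera (adjusted p = 0.00328 and 0.00512, and adjusted p = 0.78 and 0.729 with an estimated correlation), the histones not in run 1 alone (0.297).

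Some secreted factors and stromal genes were also called in hematopoietic libraries, where stromal RNA made up 10.6% of wild type and 11.3% of knock-in counts. Of 20 factors that maintain blood stem cells 3 rose and 5 fell by edgeR. Of 14 chemokines 4 rose and 3 fell, and of 23 stromal markers 1 rose and 1 fell. Camera called none of these lists (adjusted p = 0.319, 0.749 and 0.766). The chemokine Cxcl12 went from 54.9 ± 18.8 to 16.3 ± 4.51 CPM (SD, n = 6 each; log2 fold change -1.75, SE 0.27, adjusted p = 0.00109 by edgeR) and the stem cell factor gene Kitl from 23.3 ± 5.4 to 8.29 ± 3.05 CPM (-1.49, SE 0.24, adjusted p = 0.0011 by edgeR). Tnfsf11 rose by 1.69 (SE 0.39, adjusted p = 0.0107), Tnfrsf11b fell by 1.597 (SE 0.38, adjusted p = 0.014) and Runx2 fell by 0.39 (SE 0.12, adjusted p = 0.0432). Runx2 lost its call without any 1 of wild type replicates 1 to 4 or knock-in replicates 1, 2, 3, 4 and 6, with adjusted p-values up to 0.108, and in 1 fit of all 24 libraries (0.0797). Without the filter on low counts Tnfrsf11b was not called (0.0567). After the stromal subtraction Cxcl12, Tnfsf11 and Tnfrsf11b had too few counts to be tested, Kitl was at -0.82 (adjusted p = 0.636 by edgeR) and Runx2 at -0.20 (adjusted p = 0.901). Of 16 osteoblast genes 4 fell (8 adjusted over the list alone), including the transcription factor Sp7 (-1.39, not called without the filter, 0.0608). Camera called the list (adjusted p = 0.00917, and adjusted p = 0.729 with an estimated correlation) but not in run 2 alone (0.105) or after the subtraction (0.265). There Sp7 stood at -1.84 (adjusted p = 0.299 by edgeR), a size that counts stopped at 0 can inflate. By contrast Vegfc, a growth factor of lymphatic vessels, rose by 3.62 (SE 0.44, adjusted p = 0.000279 by edgeR) and kept its call after the subtraction (adjusted p = 0.00294 by edgeR). Its value there, 5.45, can be inflated by counts stopped at 0 as well. Complement C3 rose from 43.0 ± 13.9 to 184 ± 77.6 CPM (2.09, SE 0.28), the neutrophil chemokine Cxcl1 by 2.28 and Cxcl2 by 1.499 on the log2 scale. Fosl2 (1.69) and Fos (0.91), immediate early AP-1 genes, rose as well, though Fos was not called in 1 fit of all 24 libraries (adjusted p = 0.0747 by edgeR). Of 23 immediate early genes 4 rose and 2 fell, and of 16 complement genes 3 rose and 3 fell. Camera called neither list (adjusted p = 0.761 and 0.904).

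The third comparison asked what the knock-in changed in mesenchymal cells. By edgeR 10 of 19 genes of bone-forming osteoblasts fell, as did 5 of 13 adipocyte genes and 7 of 20 genes for factors with which marrow stroma maintains blood stem cells. These lists passed camera at its preset correlation and fry (fry adjusted p = 0.0383, 0.000462 and 0.00284). They did not pass camera with an estimated correlation (adjusted p = 0.499, 0.18 and 0.18). Fry called 5 of the 11 lists that camera called, the others being the cartilage and MHC class I lists (fry adjusted p = 0.0383 each). The adipokine Adipoq from 5.4 ± 2.59 to 0.0913 ± 0.12 CPM, and Cxcl12 from 1130 ± 413 to 341 ± 55.1 CPM. RANKL transcripts rose and those of its decoy receptor fell. Of 13867 tested genes, edgeR's quasi-likelihood test called 477 higher and 531 lower at a Benjamini-Hochberg adjusted p under 0.05, 1008 in all, with at least a 2-fold change for 118 and 217. Without knock-in mesenchymal replicate 1 the count was 646, and the runs fitted alone gave 391 genes in run 1 and 76 in run 2. Neither run alone called Tnfsf11, Runx2, Atp6v0d2, Slc9b2, Panx3, Ibsp, Dlx3, Mvd, Fdft1, H2-D1 or Iigp1 (adjusted p-values from 0.0641 to 0.366), which all 12 libraries did, and Negr1 was not called in run 1 (0.0641) and not tested in run 2. In 45 of the 70 named genes, which were picked among the called ones, all 6 knock-in libraries lay beyond every wild type library in the direction of the change, and in all 70 beyond the wild type mean.

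Sh3bp2 averaged 7.58 ± 0.977 CPM in knock-in mesenchymal cells (SD, n = 6), a log2 fold change of 0.04 (SE 0.12, adjusted p = 0.897 by edgeR). Ptprc was at 0.12 (adjusted p = 0.926), Ly6a at 0.16 (adjusted p = 0.746) and Csf1 at -0.18 (SE 0.10, adjusted p = 0.326) in the same edgeR fit, and Tnf had too few counts to be tested. Tnfsf11 (ENSMUSG00000022015, chromosome 14, 78277445 to 78308043) went from 10.0 ± 3.43 to 20.1 ± 4.85 CPM (SD, n = 6 each; log2 fold change 1.01, SE 0.23, adjusted p = 0.0187 by edgeR). Tnfrsf11b (ENSMUSG00000063727, chromosome 15, 54250619 to 54278484) went from 217 ± 26.8 to 116.5 ± 15.7 CPM (-0.89, SE 0.11, adjusted p = 0.000464 by edgeR). Tnfsf11 was not called in either run alone (adjusted p = 0.237 and 0.0914) or without the filter on low counts (0.0507). Runx2 fell by 0.59 on the log2 scale (SE 0.14, adjusted p = 0.0219 by edgeR, and 0.0542 without wild type replicate 1).

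Of 19 osteoblast genes 10 fell by edgeR (14 adjusted over the list alone), and the list passed camera (adjusted p = 9.43e-07, and adjusted p = 0.499 with an estimated correlation). Examples were the phosphate regulator Phex (-1.48), the homeobox gene Dlx3 (-1.74, with an adjusted p of 0.0606 in 1 fit of all 24 libraries) and Kazald1 (-1.97). The osteoblast matrix gene Ibsp went from 661 ± 454 to 53.1 ± 58.9 CPM (SD, n = 6 each; adjusted p = 0.0172 by edgeR), and was not called in either run alone (0.101 and 0.258) or without the filter on low counts (0.0598). Ibsp (-3.96, SE 0.85) and Panx3 (-4.88, SE 0.86), both genes of mineralising cells, were among the 6 largest falls, with Adipoq (-5.69, SE 0.58), Negr1 (-3.79), Wdr72 (-3.24) and the kininogen gene Kng1 (-2.99). Negr1 (adjusted p = 0.023 by edgeR) was not called without wild type replicate 1 (0.0509), knock-in replicate 1 (0.0587) or knock-in replicate 3 (0.0525), or without the filter on low counts (0.0766). Of 13 adipocyte genes 5 fell (5 adjusted over the list alone), with a camera adjusted p of 6.94e-05 and an adjusted p = 0.18 with an estimated correlation. The lipoprotein lipase gene Lpl went from 211.1 ± 46.0 to 35.1 ± 15.7 CPM (SD, n = 6 each; -2.62, SE 0.26, adjusted p = 0.00022 by edgeR), the adipogenic transcription factor Cebpa was at -1.504 and the lipid droplet gene Plin4 at -1.76. Of 10 cartilage genes 2 fell (5 adjusted over the list alone; camera adjusted p = 0.00319, and adjusted p = 0.499 with an estimated correlation), led by the matrix gene Comp (-2.91).

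Niche factors, the secreted signals by which stroma holds and feeds blood stem cells, fell in 7 of 20 cases by edgeR (9 adjusted over the list alone; camera adjusted p = 4.04e-06, and adjusted p = 0.18 with an estimated correlation). Kitl went from 146 ± 57.3 to 31.6 ± 6.41 CPM (SD, n = 6 each; log2 fold change -2.15, SE 0.22, adjusted p = 0.000226 by edgeR). Cxcl12 fell by 1.72 (SE 0.22), the vessel-stabilising Angpt1 by 1.43 and the hepatocyte growth factor gene Hgf by 1.41 on the log2 scale. All 6 knock-in libraries lay below the wild type mean for each of these 4 genes.

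**Figure D3:**
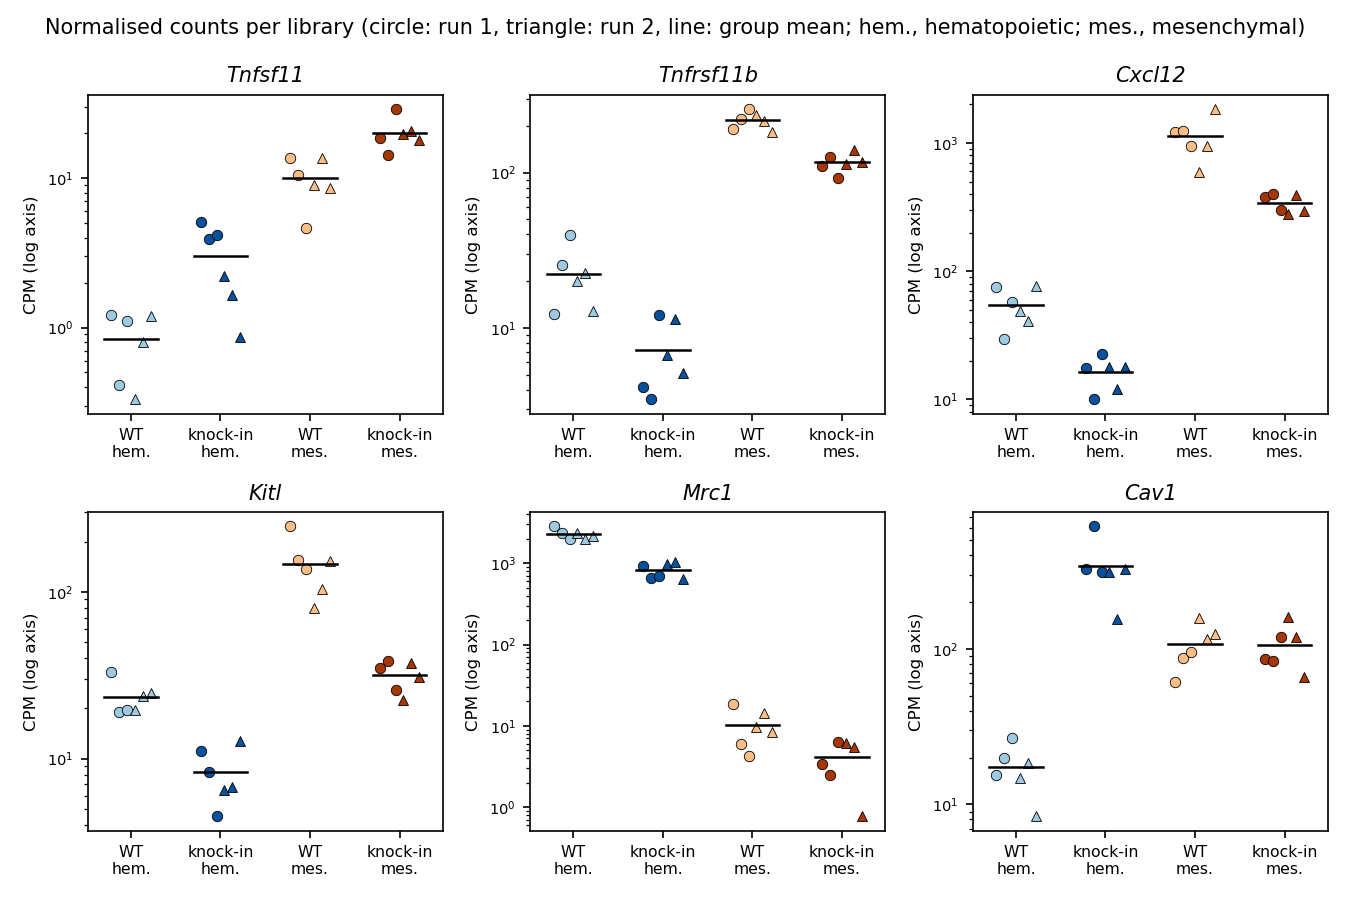
CPM on a log axis for 6 genes in each library, by genotype and population. Circles are sequencing run 1, triangles run 2, and lines the means of 6 libraries. Cxcl12 and Kitl were lower in the knock-in within both populations, Mrc1 was lower and Cav1 higher in knock-in hematopoietic cells.

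Cholesterol synthesis and antigen presentation lists were also called. Of 23 cholesterol genes 6 fell by edgeR (17 adjusted over the list alone), and camera called the list (adjusted p = 7.16e-09, and adjusted p = 0.535 with an estimated correlation). The mevalonate pathway enzyme Mvd was at -0.96 and squalene synthase Fdft1 at -0.49. Wild type replicate 6 stood apart as the highest for both. Without it they were at -0.80 and -0.39 (adjusted p = 0.0179 and 0.00768 by edgeR). Of 16 MHC class I genes 6 fell (10 lower and 1 higher adjusted over the list alone), with a camera adjusted p of 4.04e-06 and an adjusted p = 0.535 with an estimated correlation. Nlrc5, the activator of class I transcription, was at -1.23 and H2-D1 at -0.51. Interferon-stimulated genes held 1 called member of 30, the GTPase Iigp1 at -1.45, not called in 1 fit of all 24 libraries (0.0644; 5 lower adjusted over the list alone; camera adjusted p = 3.02e-06, and adjusted p = 0.865 with an estimated correlation), and run 1 alone did not call the list (0.377). The mitochondrially encoded and replication histone lists also passed camera on the lower side and the endothelial list on the higher side (adjusted p = 0.00843, 0.0116 and 0.0386, and adjusted p = 0.896, 0.97 and 0.97 with an estimated correlation). The first was not called without wild type replicate 3 (0.0558) or in run 2 alone (0.134), and the histones not without wild type replicate 2 (0.124) or knock-in replicate 4 (0.156) or in run 2 alone (0.885). The endothelial list was not called without wild type replicate 3 (0.13) or 6 (0.189) or knock-in replicate 1 (0.225), 2 (0.143), 5 (0.0809) or 6 (0.0873), nor in either run alone (0.0786 and 0.0592).

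The largest rises in mesenchymal cells included genes of osteoclasts. Mmp9, a matrix protease, went from 0.627 ± 0.351 to 18.5 ± 9.86 CPM (SD, n = 6 each; log2 fold change 4.89, SE 0.45, adjusted p = 0.000135 by edgeR). The proton pump subunit Atp6v0d2 rose by 3.92 (SE 0.67), Acp5, the tartrate-resistant acid phosphatase, by 3.60 (SE 0.63) and the sodium-proton antiporter Slc9b2 by 3.29 (SE 0.64), with edgeR adjusted p-values from 0.00528 to 0.00856. In 1 fit of all 24 libraries Slc9b2 was not called (0.0558). Hematopoietic RNA made up 0.466% of wild type and 0.641% of knock-in mesenchymal counts, and Mmp9 averaged 916 CPM in knock-in hematopoietic cells. After subtraction of that RNA, Mmp9 stood at 6.37 (adjusted p = 0.000239 by edgeR), Acp5 at 3.69 (adjusted p = 0.0532), and Atp6v0d2 and Slc9b2 had too few counts to be tested. Before it, Mmp9 held only 54 counts over the wild type mesenchymal libraries. Counts were stopped at 0, so its larger fold afterwards does not show a larger effect. The osteoclast list had 5 of 17 genes higher (6 higher and 2 lower adjusted over the list alone) and passed camera (adjusted p = 0.0195, and adjusted p = 0.535 with an estimated correlation), but not without knock-in replicate 4 (0.0743), in run 2 alone (0.0931) or after the subtraction (0.0974). Prdm1, a transcriptional repressor, rose from 0.653 ± 0.281 to 4.53 ± 0.709 CPM (2.82, SE 0.29) and C3 from 1.16 ± 0.308 to 7.7 ± 4.5 CPM (2.74, SE 0.34).

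The fourth comparison asked whether the knock-in acted differently in the populations, with the difference coded as the mesenchymal effect minus the hematopoietic effect. Single osteoclast genes rose more in hematopoietic cells. The difference for Src was -2.36 (SE 0.30, adjusted p = 4.45e-05 by edgeR), for Jdp2 -2.14, for the integrin Itgb3 -2.27 and for Nfatc1 -1.34. Of 15389 tested genes, edgeR's quasi-likelihood test called 1121, with 450 positive and 671 negative differences. Osteoclast genes were called in 6 of 23 cases, all negative (8 adjusted over the list alone; camera adjusted p = 2.53e-05, and adjusted p = 0.998 with an estimated correlation). Of 34 Toll-like receptor and NF-kB genes 10 were negative (10 negative and 1 positive adjusted over the list alone; camera adjusted p = 0.00591, and adjusted p = 0.998 with an estimated correlation), including Bcl3 (-1.20) and Nfkbia (-0.99). In the glycolysis list 3 were negative and 2 positive (5 and 2 adjusted over the list alone; camera adjusted p = 0.00591, and adjusted p = 0.998 with an estimated correlation), with Hk1 at -0.68 and Aldoa at -0.72. Of 13 adipocyte genes 3 were negative (4 adjusted over the list alone), with Lpl at -2.01 and Cebpa at -1.29, and camera called the list (adjusted p = 0.0369, and adjusted p = 0.866 with an estimated correlation) but not without knock-in mesenchymal replicate 2 (0.0694).

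The largest negative differences were in the transporters Slc6a12 (-6.50, SE 1.02) and Slc36a2 (-6.39, SE 0.78) and in Vegfc (-4.53, SE 0.51, adjusted p = 1.57e-05 by edgeR). Next came Cav1 (-4.30, SE 0.41, adjusted p = 2.43e-06 by edgeR), Tnfaip8l3 (-4.30, SE 0.97) and Lrrc39 (-3.85, SE 0.89). The largest positive ones included Cd79a (4.96, SE 1.15), the catenin gene Ctnnd2 (3.54), the transcription factor Bcl11a (3.38), Fgf13 (2.97) and Nat8l (2.92). The B lineage list had fewer than 5 tested genes in mesenchymal cells, so the value for Cd79a may rest on few counts there. The bone-remodelling pair gave no call, at -0.79 for Tnfsf11 (SE 0.48, adjusted p = 0.405 by edgeR) and 0.73 for Tnfrsf11b (SE 0.38, adjusted p = 0.311). Sh3bp2 was at -0.11 (adjusted p = 0.789) and Runx2 at -0.19 (adjusted p = 0.734).

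Some genes moved the same way in both populations. Of 12730 genes tested in both, 109 were higher in the knock-in in both and 115 lower in both, against 37.9 and 30.0 for independent lists (Fisher's exact test across genes, p = 3.84e-25 and 3.27e-38, two-sided). Opposite calls numbered 30 and 22, against 39.5 and 28.8 (Fisher's exact p = 0.126 and 0.202). Across genes the fold changes had a Pearson correlation of 0.359, and genes are not independent replicates. Culture numbers in the file names link some libraries of both populations, and deviations shared within a culture could also raise this overlap. The numbers for independent lists and the Fisher p-values take no account of that. Cxcl12, Kitl, Tnfrsf11b, Tnfsf11 and C3 belonged to the shared set, and the share of stromal RNA in hematopoietic libraries given above applies to the first 4, which are mesenchymal transcripts. After both subtractions 96 genes were called the same way in both populations.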

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

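The test of other osteoclast genes in mesenchymal libraries, the subtraction of the other population's RNA and the fit without libraries of high stromal share were chosen only after the result was seen. Of 224 groups of 6 libraries examined for a single library far from the other 5, 23 had one. Chance alone gives about 1 in 20 groups where values are normally distributed. CPM values need not be, so the chance rate here is not known.

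The single libraries were spread over genes and groups. In knock-in hematopoietic cells, replicate 6 was highest for Tnf (46.3 CPM), Mmp9 (1708 CPM), Slc7a11 (279 CPM) and Lrrc39 (6.09 CPM). Replicate 5 of that group was highest for Herc6 (26.8 CPM), Mx1 (26.6 CPM) and Fcgr1 (86.9 CPM), and replicate 2 for Vegfc (116 CPM). Its replicate 3 held the most stromal RNA, 22.99% of counts. In wild type hematopoietic cells, replicate 3 was lowest for Sh3bp2 (158 CPM). Replicate 2 stood apart for Ly6a (32.3 CPM) and Slc36a2 (3.65 CPM), replicate 6 for Slc14a1 (9.02 CPM) and C3 (70.1 CPM), and replicate 1 for Fgf13 (57.5 CPM). In wild type mesenchymal cells, replicate 6 stood apart for C3 (1.76 CPM), Kng1 (55.5 CPM), the interferon GTPase Iigp1 (20.2 CPM) and the cholesterol genes Mvd (16.3 CPM), Fdft1 (87.4 CPM) and Hmgcs1 (297 CPM), and replicate 2 for Bmp2 (1.69 CPM). Knock-in mesenchymal replicate 5 was highest for Lpl (65.6 CPM).

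Among genes named in the text, 33 had knock-in effects that differed between the populations by edgeR's interaction test. For osteoclast genes the mesenchymal effect minus the hematopoietic one was -2.36 for Src, -2.14 for Jdp2, -2.27 for Itgb3, -1.34 for Nfatc1 and -0.57 for Clcn7. In inflammatory signalling it was -1.20 for Bcl3, -0.99 for Nfkbia, -1.73 for Traf1 and -1.55 for Fosl2. Cytokine genes gave -2.53 for the chemokine Ccl9 and -2.01 for the interleukin 1 antagonist Il1rn. Metabolic and stress genes gave -0.72 for Aldoa, -0.68 for Hk1, -2.71 for Mt2 and -1.81 for Slc7a11. Slc7a11 kept its call only in the fits without knock-in hematopoietic replicate 1, 4 or 5 or wild type mesenchymal replicate 6, with adjusted p-values up to 0.1 in the other 20 fits and 0.137 without the filter on low counts. Antigen presentation genes gave -0.62 for H2-D1 and -1.13 for Nlrc5, and adipocyte genes -1.29 for Cebpa and -2.01 for Lpl. Matrix and growth factor genes gave -3.21 for Comp and -2.20 for Bmp2. The remaining negative differences were -6.50 for Slc6a12, -6.39 for Slc36a2, -4.53 for Vegfc, -4.30 for Cav1, -4.30 for Tnfaip8l3 and -3.85 for Lrrc39. Positive differences were 4.96 for Cd79a (SE 1.15, with the limit given above), 3.79 for Cecr2, 3.54 for Ctnnd2, 3.38 for Bcl11a, 2.97 for Fgf13 and 2.92 for Nat8l. Cecr2 kept its call only without wild type hematopoietic replicate 2, 3, 4 or 5, knock-in hematopoietic replicate 1 or 6, wild type mesenchymal replicate 1 or knock-in mesenchymal replicate 3, with adjusted p-values up to 0.0825 in the other 16 fits and 0.0549 without the filter.

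Of the 224 genes called the same way in both populations, 74 were at least 4-fold higher in mesenchymal libraries, and mesenchymal RNA in the hematopoietic libraries is a candidate source of these. After subtraction 6.76% of them, 5 genes, kept their hematopoietic call, 47 had too few counts to be tested, and the level predicted from the stromal share alone was 101.5% of that observed (quartiles 63.7% and 147.8%). In the 27 genes still tested the median size of the log2 fold change went from 1.38 to 1.602 and the median SE from 0.236 to 0.813, with a smaller fold in 10 of the 22 that lost their call, such as Kitl (-1.49 to -0.82), and no fold could be had for the other 47. For the 90 shared genes that were not higher in mesenchymal libraries the predicted level was 3.37%. A low value follows from that choice, since stromal RNA can supply only a small part of the level of such genes. That 82.2% of these kept their call adds little, since genes chosen this way can lose few counts to the subtraction. Genes chosen as at least 4-fold higher lose many counts in the same way. Of the 60 genes in between 55% kept theirs. A knock-in effect within the hematopoietic cells themselves stays open for the 74 genes, which include Cxcl12, Kitl and Tnfrsf11b, and was not tested apart from the subtraction.

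The rise of 16 osteoclast genes in knock-in hematopoietic libraries was tested against stromal RNA. The median predicted level from stromal RNA was 0.9% of that observed, with the highest, 21.8%, for Src. After the subtraction 81.2% of them, 13 genes, kept their call. This adds little, since genes with so low a predicted level can lose few counts to the subtraction. Calcr (2.53 before, 2.52 after, SE 0.73 and 0.81), Ostm1 (0.40 and 0.43, SE 0.12 and 0.15) and Oscar (2.64 and 2.66, SE 0.72 and 0.83) lost theirs because the SE widened. As a hypothesis, the knock-in may raise the osteoclast programme in CD45-positive cells of these cultures, and whether more cells of the lineage or more transcripts per cell gave the rise was not tested.

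Mmp9, Acp5 and Atp6v0d2 rose in knock-in mesenchymal libraries, where their hematopoietic levels were far higher. The level predicted from each library's leukocyte share was 33.3% of that observed for Mmp9 (range 18.4% to 36.7% over 6 libraries), 44.9% for Acp5 (32.5% to 102.7%) and 61.4% for Atp6v0d2 (43.0% to 122%). RNA of osteoclast-lineage cells could exceed the share that general leukocyte markers give, although the CD45-negative gate would remove such cells, and it would bring other osteoclast genes at 1.19% to 2.02% of their knock-in hematopoietic level, as for these 3. The 5 others with 10 CPM or more there, and under 1% of that in wild type mesenchymal libraries, had a median of 1.745%, with Dcstamp at 1.75%, Ocstamp at 1.08%, Calcr at 1.76%, Oscar at 3.99% and Tnfrsf11a at 0.573%. Carry-over and expression by mesenchymal cells themselves cannot be told apart for the 3 genes. Tnfrsf11a stood below the level needed, with 147 counts in wild type and 194 in knock-in mesenchymal libraries. The other 4 held only 21 to 42 counts each over the 6 knock-in libraries. In wild type mesenchymal libraries they held 4 (Dcstamp), 4 (Ocstamp), 5 (Calcr) and 6 (Oscar). Carry-over would give such a joint rise, but genes chosen as near absent from wild type favour low counts there.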

How the results depend on the processing

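The subtraction of the other population's RNA and the fit without libraries of high stromal share were chosen only after the result was seen. Over 7585 fits of named genes 6986 kept their side of the threshold, 572 lost a call, 27 gained one and no called value reversed. Of the uncalled values 39 changed sign, mostly those of Csf1, Tnf, Ptprc and Ly6a, and Sh3bp2 in mesenchymal cells in 2 fits. Of 2500 list fits 2319 stayed on their side, 57 lost, 122 gained and 2 reversed. The causes of the shifts below were not tested, except that run 1 or run 2 alone holds fewer libraries and the subtraction leaves fewer genes to test. Of 53 hematopoietic and 42 mesenchymal called genes of the text, 37 and 25 were called in run 1 alone, 14 and 9 in run 2 alone, 48 and 37 in 1 fit of all 24 libraries and 47 and 38 without the filter. DESeq2's size factors moved no split of calls by over 10 percentage points, but fits of single runs did. Of mesenchymal calls 47.3% were higher in the knock-in in the reported fit, 28.6% in run 1 alone and 27.6% in run 2 alone. For hematopoietic calls the shares were 56.7%, 62.05% and 73.4%.

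Hematopoietic calls, 2231 in the reported fit, were 672 in run 1 and 218 in run 2, 1612 without the 2 libraries above 15% stromal RNA, and 1745 to 2206 with single libraries left out. Mesenchymal calls, 1008, were 1645 by DESeq2's test, 391 in run 1, 76 in run 2 and 646 to 1036 with single libraries left out, lowest without knock-in mesenchymal replicate 1. Interaction calls ranged from 937 to 1166 with single libraries left out. Genes called the same way in both populations went from 224 to 759 at an unadjusted p under 0.05 and to 96 after the subtraction. Hematopoietic lists, 11 called, were 0 with an estimated correlation and 18 without the filter, mesenchymal ones 0, and interaction lists, 4 called, were 0 with an estimated correlation, 8 with DESeq2's size factors, 10 without the filter, 8 after the subtraction and 3 to 9 with single libraries left out. The cell cycle list reversed in run 1 alone in hematopoietic cells (adjusted p = 0.201) and, in mesenchymal cells, without knock-in replicate 6 (0.004998, against 0.787 with all libraries, range to 0.912).

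The replicate block, with the title's number in place of the run, gave 3315 hematopoietic, 1258 mesenchymal, 1331 interaction, 11444 wild type population and 11370 knock-in population calls, and 14, 11 and 6 lists. Deviations of same-numbered wild type and knock-in libraries from their group means correlated at 0.318 on average in hematopoietic and 0.251 in mesenchymal cells, against -0.013 and 0.039 for other pairs of a run. Single pairs went down to 0.041 and -0.035, and 3 and 2 of 6 libraries matched their own number best. With run means removed the averages were 0.309 and 0.174, and single pairs went down to 0.089 and 0.033. There hematopoietic replicates 1, 2, 3 and 6 and mesenchymal replicates 3, 4 and 6 matched their own number best. Pairs of the 2 populations went down to -0.176, so by the rule that every pair exceed 0.1 the numbers were not taken as pairs. For hematopoietic libraries the means leave a shared factor open. By the culture numbers in the file names, the 5 knock-in pairs of populations all exceeded 0.1 (0.186 to 0.342, with run means removed) and the 4 wild type ones did not (lowest 0.058). A block on these, over libraries with a partner, gave 10907 knock-in and 10287 wild type population calls against 11235 and 11304.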

Other observations

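The tests reported in this part were set before their results were seen. Wnt and bone morphogenetic protein genes of mesenchymal cells went both ways under the knock-in. Of 39 genes of the bone morphogenetic protein and TGF-beta list 5 rose and 6 fell by edgeR (7 and 7 adjusted over the list alone; camera adjusted p = 0.769). The antagonist Grem1 went from 24.8 ± 6.95 to 136 ± 60.8 CPM (SD, n = 6 each; log2 fold change 2.49, adjusted p = 0.00104 by edgeR), while Bmp2, a ligand it binds, went from 4.46 ± 1.42 to 0.647 ± 0.244 CPM (-2.78, adjusted p = 0.000135 by edgeR). Of 40 Wnt genes 5 rose and 8 fell (9 and 12 adjusted over the list alone; camera adjusted p = 0.665), with the secreted antagonists Sfrp2 at -2.14 and Sfrp1 at -1.90 and the ligand Wnt5b at 0.95.

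Chemokines of mesenchymal cells were split as well, with 3 of 9 higher and 2 lower by edgeR and a camera adjusted p of 0.918. The neutrophil attractants Cxcl5 (2.47) and Cxcl1 (1.31; adjusted p = 0.0505 by edgeR in 1 fit of all 24 libraries) rose, and Ccl9 (-1.55) and Cxcl12 (-1.72) fell, on the log2 scale. Neither run alone called Cxcl5 (adjusted p = 0.0509 and 0.0895 by edgeR) or Cxcl1 (0.206 and 0.115). Il1rn, which blocks interleukin 1, was at -2.07 (adjusted p = 0.00151 by edgeR). Complement C3 rose in both populations.

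Mitochondrial transcripts took 5.62% ± 0.704 of counts in wild type and 6.59% ± 0.93 in knock-in hematopoietic libraries (SD, n = 6 each, two-sided exact permutation p = 0.0779), and 5.29% ± 0.761 and 4.57% ± 0.708 in mesenchymal ones (exact permutation p = 0.126).

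Alleles of another strain linked to Sh3bp2 were tested as a source of calls. Within 10 megabases of the gene on chromosome 5, 18 of 134 tested genes (13.4%) were called in hematopoietic cells against 15.9% elsewhere (Fisher's exact p = 0.478), and 7 of 134 (5.22%) in mesenchymal cells against 7.29% elsewhere (p = 0.501). Calls were thus no more frequent in this window than elsewhere in either population. A shorter stretch was not tested, so effects of closely linked alleles stay open. Called genes close to Sh3bp2 included Zfyve28 in hematopoietic cells (log2 fold change 0.96, adjusted p = 0.00128 by edgeR). In mesenchymal cells they included Tnip2 (-0.42, adjusted p = 0.04 by edgeR).

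Chance was tested by splitting the libraries otherwise, with 100 splits per comparison that kept 3 libraries of each group in each run and counted the real split. The real split was the only 1 of the 100 with as many calls in every comparison, the lowest share that 100 splits can give. In the genotype comparisons so many calls were thus rare among random splits of these libraries. For the populations every other split mixed the 2 populations within a group, so that outcome was largely fixed beforehand. For the interaction the other splits mixed the genotypes, so the test cannot separate a differing knock-in effect from a shared one. The highest other split gave 84 genes against 2231 in hematopoietic cells, 2 against 1008 in mesenchymal cells, 39 against 1121 for the interaction, 7248 against 11304 for wild type populations and 7258 against 11235 for knock-in populations.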
